A study of Homo sapiens with 4 samples.

How the data were processed

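Gene expression was measured in 4 samples of BE(2)C neuroblastoma cells, 2 transfected with a non-targeting control siRNA and 2 with siRNA against SSRP1, with a cationic lipid reagent. Total RNA was isolated 72 hours later, and 100 ng of it was labelled with biotin and hybridised to Affymetrix Human Gene 2.0 ST arrays, per the labels' protocols. The deposited table holds log2 expression values per probe set, which the authors made with RMA, per the submitters' processing notes. As usually run, RMA corrects background, quantile normalizes between arrays and summarises the probes of each set. The software that ran RMA, its version and the probe set definition are not given in the sources used here. That the scale is log2 was read from the values, which run from 0.502 to 12.8 with near equal quartiles on every array. Since the distributions of the arrays were nearly alike, a shift of all transcripts in one direction would not be visible. The table has 1 column per array, all 4 were used, and no detection or background values were used here. A dim probe set can therefore reflect background as well as RNA, and changes from dim levels are compressed.

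Probe sets were named through the platform annotation, with symbols taken from the RefSeq gene table of GRCh38.p14 through the gene ID. Of 46255 probe sets, 15835 had 1 gene symbol, 0 had several and 30420 were unnamed here. Every gene ID of the named probe sets was found in the RefSeq table, and 0 symbols changed. The named sets covered 14812 genes. For the 651 genes with several probe sets the one with the highest mean over the 4 arrays was used. In 261 of these genes the probe sets had changes of both signs, and none of the genes named in the text under the rule below had several. No coordinates are given, since the annotation's build is not stated. The unnamed probe sets were left out of the main test and enter only the alternative over all probe sets and the closing section.

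Samples were grouped by their titles. The main test was limma (version 3.58.1 in R 4.3.3), with lmFit and eBayes without an intensity trend and without robust estimation, on the deposited log2 values of all 4 arrays, SSRP1 siRNA minus control siRNA. No filter on dim genes and no block were used. P-values were adjusted with the Benjamini-Hochberg method over all genes, and a gene passed the test at an adjusted p under 0.05. The fit had 2 residual degrees of freedom per gene and 3.79 prior degrees of freedom. All p-values of single genes are from this test and are two-sided, and 95% intervals use its standard errors.

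Data were simulated from the real means, with independent genes and with spreads drawn from the fitted prior regardless of level. With 200 changed genes among 14812 in 20 runs, the test called 2.5% of genes changed by 0.5 on the log2 scale. It called 72.2% of those changed by 1, 92.6% of those changed by 1.5 and 97.5% of those changed by 2. Of the calls 4.61% were unchanged genes. In the real data 57 genes had a measured change of at least 2-fold and 14 genes passed, so these shares may not carry over. In runs with no shifted list camera called a list in 1 of 20, again with independent genes, so this does not cover correlated lists.

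The genes named in the text were chosen by rule. SSRP1, SUPT16H and MYC were always named, and 1 further gene of this part is not analysed here. The 10 largest rises and the 10 largest falls were named among genes past the test whose groups did not overlap and whose mean lay above the median of all genes (4.63). Where fewer than 10 passed in a direction, the genes with the smallest unadjusted p in that direction were added and named as not past the test. For each list the 3 members with the largest change among those past the test were named, or the 1 with the smallest p where none passed. Other genes named as examples were chosen after their values were seen.

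Of 26 gene lists, 24 were tested and 2 are not analysed here. They held 523 measured members of 926 fixed, counting a gene once per list, so a list's result covers only its measured part. The lists were tested with camera at a preset correlation of 0.01 between genes, with adjustment over the lists. camera with an estimated correlation and the rotation test fry were run beside it. With an estimated correlation camera works on the 2 residual degrees of freedom, so small p-values are hard to reach whatever the correlation. Members were also adjusted over the list alone.

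The alternatives were the replicate number as a block, a variance trend, robust variance estimation, quantile normalization, centring on each array's median, the mean of a gene's probe sets, only genes at or above the median level, each array left out in turn, all probe sets, a minimum of 1.5-fold or 2-fold change and an adjusted p under 0.1. For the lists, genes in more than 1 list were also left out. Bootstrap intervals in the closing section use 10000 draws over genes for medians. All bootstrap intervals there resample genes only and hold no spread between arrays.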

Results

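RNA was measured in BE(2)C cells, an established human neuroblastoma line, after transfection with a non-targeting control siRNA or with siRNA against SSRP1. SSRP1 is a subunit of FACT, the histone chaperone that takes apart and rebuilds nucleosomes ahead of and behind the polymerases, and its partner in that complex is SUPT16H. Each group held 2 samples, and each sample was hybridised to 1 whole-transcript array, which makes 4 arrays. RNA was taken 72 hours after transfection. The median log2 value over the 46255 probe sets was 3.40 and 3.42 on the control arrays and 3.37 and 3.41 on the SSRP1 siRNA arrays. Pearson correlations over all probe sets lay at 0.993 between the control arrays, at 0.991 between the SSRP1 siRNA arrays and between 0.990 and 0.991 across the groups. The number of arrays limits the precision of each value below. The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

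The siRNA target was examined first. SSRP1 fell from a log2 value of 9.14 ± 0.13 (SD, n = 2) with control siRNA to 7.20 ± 0.32 (SD, n = 2) with SSRP1 siRNA. The log2 change was -1.95 ± 0.17 (SE), which left 26.0% of the control level with a 95% interval of 19.3 to 34.8%. The limma adjusted p was 0.0479, and both SSRP1 siRNA arrays (7.42 and 6.97) lay below both control arrays (9.05 and 9.23). The value comes from probe set 16738429, which names gene ID 6749. SUPT16H, the other FACT subunit, had a log2 change of -0.07 ± 0.10 (SE), with group means of 9.79 and 9.71 and an adjusted p of 0.821. The 95% interval of that change ran from -0.32 to 0.17. Without any 1 of the 4 arrays the SSRP1 change lay between -2.17 and -1.72 and the adjusted p between 0.241 and 0.599, in fits with 1 residual degree of freedom. With robust variances the adjusted p was 0.0512.

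The comparison of SSRP1 siRNA with control siRNA asked which other transcripts differed when the target was depleted. Genes of cell surface receptors, secreted factors and transcription factors were among those that rose. CALCRL, the receptor subunit for calcitonin gene-related peptide and adrenomedullin, rose most, from 3.75 to 6.78, a log2 change of 3.03 ± 0.19 (SE, adjusted p = 0.0267). EDNRB, the endothelin B receptor needed for neural crest development, rose from 5.83 to 7.84, a log2 change of 2.01 ± 0.15 (SE, adjusted p = 0.0356). KLF2, a zinc finger transcription factor induced by blood flow in vessel walls, rose from 5.93 to 7.55, a log2 change of 1.62 ± 0.10 (SE, adjusted p = 0.0267).

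Smaller rises were seen for other cell surface and signalling genes. GPR83, a G protein-coupled receptor of the brain, rose by 1.60, and NPY2R, a receptor for neuropeptide Y, rose by 1.57 on the log2 scale from an already high control level of 7.53. CXCR4, the receptor for the chemokine CXCL12, rose by 1.36. NOTCH1, a receptor of the Notch pathway, rose by 1.33, and ANGPT2, a secreted ligand of the TIE2 receptor, rose by 1.34. The secreted glycoprotein gene CRISPLD2 rose by 1.45, and MBOAT4, which encodes the enzyme that acylates ghrelin, rose by 1.39. GFRA3, the artemin co-receptor, rose by 1.56 from a low level of 2.69 to 4.25. These genes had standard errors between 0.097 and 0.125 and adjusted p between 0.0267 and 0.0493. ZNF792, a zinc finger gene, rose by 1.11; it lies outside the rule for named genes and was chosen after its value was seen.

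ARHGEF28, a guanine nucleotide exchange factor for RhoA, was the only gene besides SSRP1 that was lower and past the test. It fell from 6.18 to 4.55, a log2 change of -1.63 ± 0.12 (SE, adjusted p = 0.0356). The 8 further genes lower with SSRP1 siRNA that had the smallest p did not pass the test. Among these, the receptor genes CYSLTR2 (cysteinyl leukotrienes), HRH3 (histamine) and CNTFR (ciliary neurotrophic factor) had log2 changes of -1.78, -1.14 and -1.11. SOSTDC1, a secreted antagonist of BMP signalling, had a change of -1.02, and the ephrin gene EFNA4 a change of -0.92. HEATR5A, CKAP4 and the kinase gene PIM1 had changes of -1.23, -0.97 and -0.94. The adjusted p of these 8 genes lay between 0.0539 and 0.0839.

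In all, 14 of 14812 genes passed the limma test at an adjusted p under 0.05, 12 higher and 2 lower. The smallest change among them was 1.11 in size on the log2 scale, and the median SE over all genes was 0.117. At an unadjusted p under 0.05 there were 1865 genes (12.6%), 972 higher and 893 lower. A change of at least 2-fold was measured for 49 genes upward and 8 genes downward, whether past the test or not. The groups did not overlap for 6557 genes (44.3%), where chance gives 33.3%. No gene passed when any 1 array was left out, with a smallest adjusted p between 0.241 and 0.599 and 1200 to 1672 genes at an unadjusted p under 0.05. The count was 9 with robust variances, 0 over all probe sets (3854 at an unadjusted p under 0.05) and 215 with a variance trend, 143 of them higher, while 19 of 28 genes were higher after quantile normalization and 17 of 23 after median centring.

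**Figure D1:**
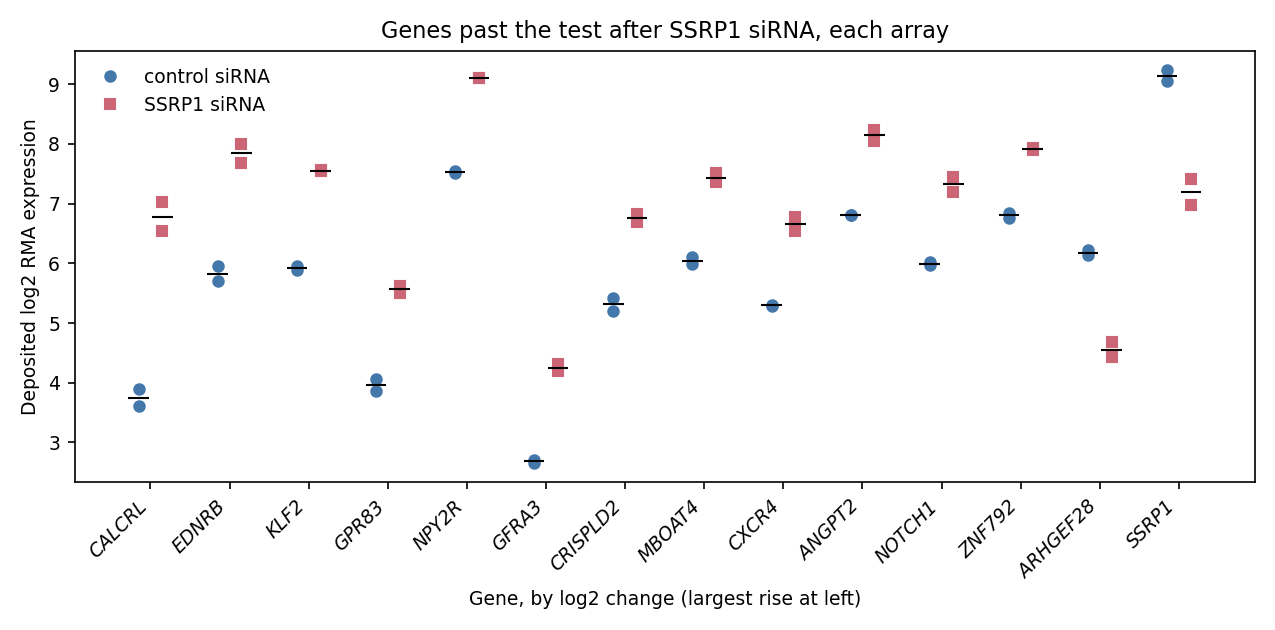
Log2 expression (vertical axis, deposited RMA values) of the 14 genes past the test (horizontal axis, ordered by change) on each of the 4 arrays, with circles for control siRNA, squares for SSRP1 siRNA and a bar at each group's mean. CALCRL has the widest gap, from 3.75 to 6.78, and only ARHGEF28 and SSRP1 are lower with SSRP1 siRNA.

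Gene groups relevant to this cell line and treatment were compared as lists fixed before the data were examined, as were the tests and the rule for named genes. Growth factor and stress inducible immediate early genes were higher as a group with SSRP1 siRNA. The mean log2 change over the 26 measured members was 0.24 and the median 0.17, with 16 members above 0. KLF2 was the 1 member that passed over all genes tested, and 7 members, all higher, passed when adjusted over the list alone. Besides KLF2 these were EGR1 (0.98), ATF3 (0.74), SPRY2 (0.69), KLF10 (0.45), SPRY4 (0.44) and IER2 (0.41), which were named after their values were seen. FOS and JUN, the AP-1 genes usually induced with them, had log2 changes of 0.14 and 0.03. camera gave an adjusted p of 0.00314 for the list at its preset correlation. With an estimated correlation, -0.004 for this list, camera gave an unadjusted p of 0.0506 and an adjusted p of 0.791. All 24 lists shared that adjusted p, so it does not rank them. The estimate lay below the preset of 0.01, so a larger correlation is not why the p rose. The estimated setting works on 2 residual degrees of freedom.

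Genes of G2/M and mitosis were lower as a group by a small amount. The mean log2 change over 39 measured members was -0.11 and the median -0.13, and 33 of the 39 members lay below 0. None passed over all genes or when adjusted over the list alone in limma, and 4 had an unadjusted p under 0.05. These were MKI67, the proliferation marker Ki-67, at -0.42, KIF23, a kinesin of the central spindle, at -0.35, and AURKB and CDCA3 at -0.27 each. camera gave an adjusted p of 0.00326 at the preset correlation of 0.01. The estimated correlation of this list was higher, at 0.117. With it, and on 2 residual degrees of freedom, camera gave an unadjusted p of 0.208 and an adjusted p of 0.791. In the DNA replication and E2F target list 21 of 32 members lay below 0, with a mean of -0.05 (-0.096 without SSRP1 siRNA replicate 1 and -0.01 without SSRP1 siRNA replicate 2) and a camera adjusted p of 0.353, and DSCC1, a subunit of an alternative clamp loader, had the smallest p at -0.42. The DNA repair list had a mean of -0.07 (adjusted p = 0.508), with the checkpoint kinase gene ATR at -0.33, and that mean ran from -0.14 without SSRP1 siRNA replicate 1 to 0.004 without SSRP1 siRNA replicate 2. The call for immediate early genes was lost without control replicate 2 (adjusted p = 0.0733). The call for mitosis was lost without control replicate 2 (adjusted p = 0.0748) or SSRP1 siRNA replicate 2 (adjusted p = 0.194, mean -0.07).

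MYC-linked genes did not stand apart from other genes. The MYC transcript itself was dim in both groups, at 2.20 and 2.10, with a change of -0.10 ± 0.14 (SE, adjusted p = 0.819). Of 26 measured MYC-induced genes, 10 lay above 0 and 16 below, with a mean of -0.03, a camera adjusted p of 0.558 and none past the test. The smallest p in that list belonged to CDK4, a kinase of the G1 phase, at 0.25, and ODC1, the rate-limiting enzyme of polyamine synthesis, had a change of -0.21. The MYC-repressed list had a mean of -0.07 (adjusted p = 0.558) and 4 of 17 members past the test when adjusted over the list alone, in both directions. These were SFRP1 (-0.68), NDRG1 (-0.86), CLU (-0.47) and BIN1 (0.57). The polyamine synthesis and transport list had a mean of -0.02 (adjusted p = 0.75), with AGMAT at 0.39. In the list of FACT and other histone chaperones SSRP1 was the 1 of 19 members that passed. Its mean was -0.05 and its median 0.03, opposite in sign (adjusted p = 0.679), and the elongation factor gene SUPT6H had a change of 0.37.

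Neuroblastoma cell state genes moved in both directions. In the adrenergic list 4 members were higher and 1 lower when adjusted over the list alone and none of 32 passed over all genes, with a mean of 0.04 (adjusted p = 0.640). The noradrenaline-synthesising enzyme gene DBH had a change of -0.77, against 0.87 for HEY1, 0.54 for INSM1 and 0.43 for DDC. In the mesenchymal list 2 members were higher and 2 lower when adjusted over the list alone and none of 35 passed over all genes, with a mean of -0.002 (adjusted p = 0.679). CREG1 and the intermediate filament gene VIM had changes of 1.19 and 0.76, against -0.63 for SOX9 and -0.58 for SNAI1. In the neuronal maturation list the mean was 0.03 and the median -0.002, opposite in sign (adjusted p = 0.699). Its members DCX, a microtubule protein of migrating neurons, and NRCAM had changes of 0.86 and 0.50, and the filament gene PRPH a change of -0.54.

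Stress and metabolic lists gave no camera call and had no member past the test over all genes. The p53 target list had a mean of 0.08 (adjusted p = 0.558), and TP53INP1 (1.17) and SESN1 (0.50) passed when adjusted over the list alone. The ATF4 and unfolded protein response list had a mean of 0.08 (adjusted p = 0.482), with ATF3 and VLDLR (0.92) past the test when adjusted over the list alone. The hypoxia and glycolysis list had a mean of 0.04 (adjusted p = 0.482), with CA12 at 0.71 and NDRG1 at -0.86 in opposite directions. Cholesterol synthesis genes had a mean of -0.09 (adjusted p = 0.197), with STARD4 at -0.47. Interferon response genes had a mean of 0.07 (adjusted p = 0.482), with OASL at -0.32, and that mean was 0.027 without SSRP1 siRNA replicate 2 and 0.11 without SSRP1 siRNA replicate 1. NF-kB target genes had a mean of -0.03 (adjusted p = 0.482), with CFLAR at 0.27.

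The remaining functional lists also gave no camera call. Heat shock genes had a mean of 0.14 (adjusted p = 0.538), with HSPB1 at -0.25 the member of smallest p, and that mean ran from -0.026 without SSRP1 siRNA replicate 1 to 0.30 without SSRP1 siRNA replicate 2. Apoptosis regulators had a mean of 0.02 (adjusted p = 0.712), with the anti-apoptotic gene MCL1 at 0.43. Cytosolic ribosomal protein genes had a mean of 0.08 (adjusted p = 0.106) and 32 of 42 members above 0, with RPS15A at 0.45. Housekeeping reference genes had a mean of 0.025 (adjusted p = 0.679), with EMC7 at 0.33.

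Markers of other cell types that a culture could hold were measured beside these groups. Of 9 Schwann and glial markers GFRA3 was higher and passed over all genes, and S100B (0.47) passed only when adjusted over the list alone. The mean of this list was 0.26 (camera adjusted p = 0.106). The median of this list was 0.04, with 5 members above 0 and 4 below. The rotation test fry, which asks whether a list moves one way on balance, called this list alone, with an adjusted p of 0.0102, and its mixed form, which asks for change in either direction, called 14 lists. Of 7 fibroblast and stroma markers none passed over all genes, and the matrix proteoglycan gene LUM (1.20) passed when adjusted over the list alone, with a list mean of 0.25 (camera adjusted p = 0.316) that was 0.14 without control replicate 2 and 0.36 without control replicate 1. Of 8 blood and endothelial markers none passed either way, with a mean of -0.05 (camera adjusted p = 0.671), and the T cell gene CD2 had the smallest p at -0.27. Of the 24 lists tested camera called 2 at the preset correlation and none with an estimated correlation, where the lowest adjusted p was 0.791. With that setting a list shifted by 0.3 was called in 0 of 20 simulated runs, against 20 of 20 at the preset correlation. On 2 residual degrees of freedom such a list could hardly be called, so the lack of calls is no evidence against a list. The shift of 0.3 was larger in size than the means of the 2 called lists (0.24 and -0.11). The simulated genes were independent, so these runs do not test the preset on correlated genes. The G2/M and mitosis list had an estimated correlation of 0.117.

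**Figure D2:**
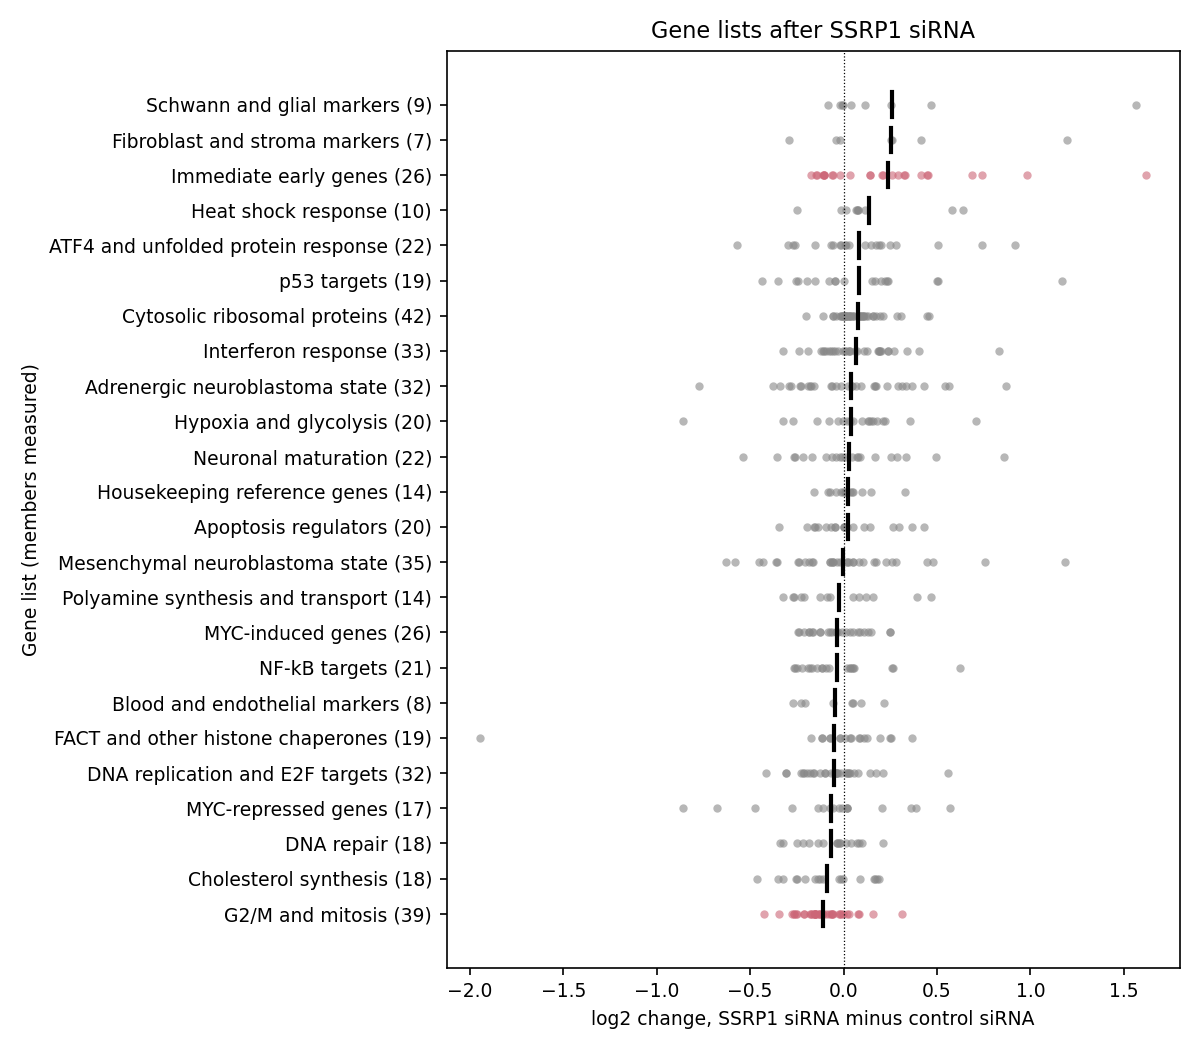
Log2 change with SSRP1 siRNA against control siRNA (horizontal axis) of every measured member (points) of the 24 gene lists (vertical axis, number of members in brackets), with a bar at each list's mean and in colour the 2 lists that camera called at the preset correlation. Immediate early genes have a mean of 0.24 and G2/M and mitosis genes a mean of -0.11.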

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

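The tests on unnamed probe sets alone were chosen after other results had been seen. Probe sets without a gene name here were left out of the comparisons, and 2 of these 30420 passed limma's test when fitted alone, both higher with SSRP1 siRNA and above both control arrays. Probe set 16975302 rose from 0.82 to 4.09, a log2 change of 3.27 ± 0.18 (SE, adjusted p = 0.0484). Its control values, 0.71 and 0.94, lay near the lowest values on those arrays, 0.64 and 0.59. The size of that change therefore depends on the background. Probe set 17010782 rose from 3.49 to 6.04, a log2 change of 2.55 ± 0.14 (SE, adjusted p = 0.0484). In the fit over all 46255 probe sets both had an adjusted p of 0.0783. The transcripts they measure were not looked up, and no explanation was tested.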

How the results depend on the processing

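All alternatives were fixed beforehand, and no tests were added in this part. The 14 genes became 215 with a variance trend, 28 after quantile normalization and 23 after median centring, and each of these held the 14. At an adjusted p under 0.1 in limma there were 41, which hold the 14 by definition. With genes at or above the median level alone, where fewer genes were tested and the variance prior was refitted, the count was 179, with 13 of the 14. It was 9 with robust variances, all among the 14. Over all 46255 probe sets, where more features were tested and the variance prior was refitted, it was 0. The smallest adjusted p in limma there was 0.0783, and 3854 probe sets had an unadjusted p under 0.05. The mean of a gene's probe sets and a minimum of 1.5-fold or 2-fold gave 14. The fold minima could remove no gene, since the smallest change among the 14 was 1.11 in size on the log2 scale. Averaging could not move the values of genes named under the rule, since none had several probe sets. Leaving out each array gave 0 in every case, with 1 residual degree of freedom. With the replicate block the count was 6, with 5 of the 14, and the SSRP1 change was -1.95 with an adjusted p of 0.0569. The labels do not say that the numbers pair the samples, and deviations of same-numbered arrays correlated at 0.114 over all genes and at 0.23 over genes at or above the median level.

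The SSRP1 change was -1.95 with robust variances too (adjusted p = 0.0512), and lay between -2.17 and -1.72 without 1 array, where it did not pass. The cause of the differences between variance settings was not tested. Of 24 lists, 2 were called under the block, the variance trend, both scalings, the mean of probe sets, the filter on dim genes and without shared genes. Robust variances did not enter the list test, so they are no alternative for it. Without 1 array the number ran from 0 to 2, with an estimated correlation it was 0, and with fry it was 1, a list other than the 2. The mean of the G2/M and mitosis list was -0.11 with an estimated correlation (adjusted p = 0.791) and with fry (adjusted p = 0.321), and lay between -0.152 and -0.072 without 1 array. The mean of the immediate early list was 0.24 with an estimated correlation (adjusted p = 0.791) and with fry (adjusted p = 0.129), and lay between 0.21 and 0.27 without 1 array. No result changed sign while called. Without 1 array the mean moved by over 1.5 times in 18 of the 24 lists, all but the immediate early, MYC-repressed, ATF4, cholesterol, ribosomal and Schwann lists. It took both signs in 7, none of them called: DNA repair, heat shock, hypoxia and glycolysis, mesenchymal state, NF-kB targets, neuronal maturation and polyamine synthesis. Over single named genes and settings, 367 values kept their side of the threshold, 58 no longer passed and 39 newly passed, and 1 list not called before was called. The fits for 1 gene not analysed here were not run. No background values were used, so how signal over background limits dim genes was not measured.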

Other observations

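Of the tests below, the split of the arrays and the receptor test over all receptor genes were chosen only after the result was seen. The lists of endothelial and Notch genes were written after some of their members' values were known, and their tests used members not yet seen, except where stated.

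Several genes of the endothelial and vascular list, which was written after some values were known, were higher with SSRP1 siRNA. Besides CALCRL, EDNRB, KLF2, CXCR4, NOTCH1 and ANGPT2, which rose, FLI1, a transcription factor of the endothelial lineage, and ECSCR, an endothelial surface protein gene, had log2 changes of 1.35 and 1.48 without passing the test. Also not past the test, the ephrin receptor gene EPHB4 had a change of 1.25, the junction gene ESAM 1.08, the coagulation inhibitor gene TFPI 1.22 and the ligand gene ANGPT1 1.02. Members not seen before the list was written included MYCT1 (1.29), ICAM2 (0.81), PODXL (0.74), ACVRL1 (0.72), ETS2 (0.69) and ERG (0.68) on the higher side and GPR4 (-0.83) and NRP2 (-0.65) on the lower side. The endothelial genes VWF (-0.06), KDR (0.09), CLDN5 (-0.14) and FLT1 (0.001) had changes closer to 0. Their mean levels (3.1, 2.9, 4.60 and 4.4) lay below the median of all genes (4.63). The list of blood and endothelial markers fixed beforehand showed no rise. Its mean was -0.05, with 4 of 8 members above 0 and 4 below (camera adjusted p = 0.671). ADRA2A, the alpha-2A adrenergic receptor, had a change of 2.25 with an adjusted p of 0.0583.

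A shared rise of endothelial genes is a hypothesis from these data: the 51 members not seen before ranked higher than other genes by camera (one-sided p = 0.0124, or 0.0699 with an estimated correlation), but their median change was 0.051, with a 95% bootstrap interval of -0.05 to 0.22. Endothelial cells in the SSRP1 siRNA cultures would bring all their abundant transcripts. The median of 11 abundant ones not seen before was 0.22 (interval 0.001 to 0.39), under the 0.5 that was set beforehand. Of these, MMRN1 (mean level 2.9), TIE1 (2.9), CD34 (3.8), CD93 (3.9) and PLVAP (4.0) were dim, where changes are compressed. FLT1 (4.4) and CLDN5 (4.60) also lay below the median level of all genes (4.63). RAMP2 (5.7), AQP1 (5.7), ENG (8.0) and ICAM2 (8.7) lay above that level. A small share of such cells therefore stays open. Dependence on a single array stays open, since the mean of the 51 members was 0.13 with all arrays and 0.086 without SSRP1 siRNA replicate 1, the lowest value. A set of 14 risers among the 19 members seen before had a mean of at least 1.26 without any 1 array, but they were picked for their change and test nothing. Off-target effects of the single siRNA stay open too: the labels give 1 catalogue number for SSRP1 siRNA, the design text speaks of siRNAs in the plural, and no group separates such effects from SSRP1 loss.

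The higher level of immediate early genes was weighed against technical causes. Scale differences left between the deposited arrays are argued against as the whole cause, since the mean was 0.235 after quantile normalization (adjusted p = 0.00179) and 0.26 after median centring (adjusted p = 0.00403). Quantile normalization moved the log2 change of a gene by 0.0726 at most, so a shift that the authors' own normalization removed or made was not tested. Dependence on a single array stays open, because without control replicate 2 the adjusted p was 0.0733, although the mean lay between 0.21 and 0.27 without any 1 array. The design has no group that would test a biological cause of this rise.

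Receptors coupled to G proteins were frequent at the top of the list. Of 249 receptor genes picked by symbol, outside the odorant and taste families, 10 (4.02%) had an unadjusted p under 0.001, 6 higher and 4 lower, against 0.841% of 11651 other protein-coding genes (Fisher's exact test, one-sided, odds ratio 4.93, 95% interval 2.26 to 9.61, p = 8.62e-05). The class was chosen because its members had been seen to change, so this is no independent test. Among the 236 receptor genes left after removing those with p under 0.001 and the members of the added lists, 11.4% had an unadjusted p under 0.05 against 12.2% of other genes (odds ratio 0.933, interval 0.598 to 1.40, one-sided exact p = 0.661). Other genes with p under 0.001 were removed in the same way. Because the changed receptors were taken out by their p, the bound set for this test excludes nothing, and whether the class differs from other genes stays open.

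FACT travels with RNA polymerase, so lower expression of long genes was tested as a hypothesis. Across 6914 protein-coding genes at or above the median level, which are not independent replicates, Spearman's rho between gene length and log2 change was -0.01, with a 95% bootstrap interval of -0.03 to 0.01. The split of the arrays by replicate number gave -0.22, so length moved more with the number than with the siRNA. A shared rise of Notch pathway genes beside NOTCH1 was also tested. The median change of 22 Notch genes not seen before was -0.036, with an interval of -0.11 to 0.04 that lies under the 0.1 set beforehand. That interval resamples genes and holds no spread between arrays, so it does not exclude a shared rise of that size. camera gave a one-sided p of 0.785 for these genes. Single Notch genes went both ways, with the target HEY1 at 0.87 and the ligand gene DLL3 at -0.71 among those seen before, and DTX4 at 0.56 and DTX1 at -0.38 among those not seen.

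The 4 arrays can be split into equal groups in 3 ways, too few for a share under 0.05. The real split gave 14 genes in limma and the highest of the other splits 0, with 548 and 322 genes at an unadjusted p under 0.05, so 1 of the 3 splits gave as many.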
